A study of Brassica napus with 4 samples.

How the data were processed

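Gene expression in developing seeds of oilseed rape (Brassica napus) was measured on 4 single-colour Agilent arrays, 2 labelled high in oleic acid and 2 labelled low in it. Per the labels, the plants were transgenic and self-fertilised under bags, and total RNA was labelled with Cy3; the transgene and the seed age are not given in the sources used here. The sample titles are high oleic acid line 1 and line 2, and low oleic acid line 1 and line 2. Nothing says whether the numbers stand for separate lines, separate plants or repeats. The p-values thus measure only the spread between these samples, which may be technical. Each group of 2 arrays is called a line here, although it may hold 2 lines.

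The deposited scanner files hold signal intensity per spot, extracted with Agilent Feature Extraction; the file headers give version 10.7.3.1 and the submitters' processing notes give version 9.1, and the difference is not resolved here. The scanner's flags for outlier spots, saturation and signal well above background were taken from the same deposited files. The authors also deposited a table of normalized values and a series value table, both on a log2 scale. The values of the 4 columns of each have nearly the same distribution, with medians of 6.79 in every column of the series value table, which is what quantile normalization gives; the authors' method is not given in the sources used here, and its centring is unknown. Each column of the series value table correlated with its own array's log2 scanner intensity at 0.996 to 1.00 across probes. The normalized table also has 4 columns of detection calls whose headings cannot be matched to single samples, and they were not used.

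Each array held 43603 probes after control spots were left out. The processed intensity was put on the log2 scale and the array's 75th percentile was subtracted. Spots of a probe were averaged, and spots flagged as outliers (7 to 11 per array) were left out. Probes well above background on both arrays of at least 1 line were kept, which left 32820, and 32811 of these had values on all 4 arrays and were tested. No probe was saturated. The lines were compared with limma 3.58.1 in R 4.3.3, by a linear model on group and an empirical Bayes test with an intensity trend, two-sided. A probe was called at a Benjamini-Hochberg adjusted p under 0.05, and counts with a change of at least 2-fold were added. With 2 arrays against 2, an exact permutation test of a single value cannot give a two-sided p under 0.333, so no such test was run. The number of arrays limits the precision; the median standard error of a log2 difference was 0.30. A probe not well above background on either array of a line was given as a bound: the mean of the brighter line against, for each dim array, the higher of its lowest signal among detected probes and the probe's own signal. Such a bound holds only for the processed signal on this scale; a normexp background correction with its added offset lowers the fold of a dim probe.

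All 4 arrays lay on 1 slide and in 1 scan, so there was no slide to use as a block. Spiked control probes (E1A) on the arrays were not used for the main scaling.

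The files hold no gene symbols. Names came from the array's description column, which gives the most similar protein for 14486 probes and a named mRNA record for 291; the remaining probes have a clone, a genomic sequence or no name. Some of the similar proteins belong to bacteria or animals and are printed as the files give them. Treating clone and genomic descriptions as unnamed was decided after the descriptions were seen. Of 14398 sequence accessions in the files, 0 were in the reference gene table, so no newer name was used.

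The lists of genes, the rule for named genes and the settings described next were fixed before the data were examined. A total of 20 lists covered fatty acid, oil, seed development, stress and housekeeping functions and markers of other cell types or organs; 19 had at least 3 tested probes, and the endosperm list matched 0 probes. Probes entered a list by Arabidopsis locus or by a phrase in the description. Each list was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 19 lists, and also with an estimated correlation and with fry. The probes named are the 10 with the largest change in each direction among called, named probes whose arrays did not overlap between lines, 10 desaturase probes in order of p, and the 3 probes with the smallest p of each other list. Some phrases caught unrelated proteins, such as methionine enzymes in the defence list and GEM-like proteins in the late embryogenesis list; the lists were kept, and a version with phrases matched from the start of a word was added after seeing the data.

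Alternatives were quantile normalization, median centring, the authors' tables, other filters, variance models and thresholds, a plain two-sample test, the replicate number as a block, other list rules, and each array left out in turn. Normexp with an offset of 50 was run on the median signal, because the files hold no mean signal, and this setting, scaling on the spiked controls and lists without probes below background in 1 line were added after seeing the data. With 1 array of a line left out, the residual spread came only from the pair of the other line. The high oleic arrays lay further apart than the low oleic arrays. Counts of calls from these fits thus depend on which pair was left, beside the differences themselves. The replicate numbers were not treated as pairs.

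A first version of the self-test recovered 0 of 200 changed probes. Its noise was drawn around variances the fit had already shrunk and its changes were 8-fold at most. Which of these lowered the recovery was not tested, and the version described here replaced it. The fit was tested on simulated arrays. Each probe kept its mean over the 4 arrays, and its noise was drawn from limma's own fitted variance model, equal in both lines. The recovered and false shares below hold only under that model. In the data 13.3% of probes were at least 2-fold apart between the high oleic arrays and 4.05% between the low oleic arrays. For the comparison of the lines over 32811 probes, with 200 changed it recovered 1.47% of 2-fold, 59.1% of 8-fold and 97.0% of 64-fold changes, and made 0 calls where nothing was changed. With as many probes changed as were called in the data, it recovered 50.1% of 2-fold and 98.6% of 8-fold changes, and 3.11% of its calls were unchanged probes.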

Results

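The series compared seed transcripts of rapeseed labelled high in oleic acid with those of rapeseed labelled low in it, with 2 arrays per group. Oleic acid is the monounsaturated fatty acid from which seeds make linoleic and linolenic acid, so the comparison asks which genes differ between seeds with much and little of it. Signal was well above background for 29221 and 32600 of 43603 probes on high oleic arrays 1 and 2, and for 32344 and 32917 on low oleic arrays 1 and 2. The 75th percentile of the signal was 393 and 708 on the high oleic arrays and 901 and 803 on the low oleic arrays, so high oleic array 1 was the dimmest. Across the 32811 tested probes, which are not independent replicates, the log2 signals correlated at 0.972 (Pearson; Spearman 0.977) between the high oleic arrays and 0.987 (Spearman 0.989) between the low oleic arrays. Between the lines the Pearson correlations ran from 0.797 to 0.829 and the Spearman correlations from 0.832 to 0.876.

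The lines differed over a large share of the transcripts that the array measures. Single probes for the ribosomal proteins L27-2, P1-2 and S30, a regulatory subunit of cyclin-dependent kinases and histone deacetylase 19 were bright in high oleic seeds and not well above background in low oleic seeds. Single probes for mitochondrial malate dehydrogenase 1, a 10 kDa chaperonin, ribosomal protein L4-B and the splicing protein Sm-D1 showed the opposite. In all, 6202 of 32811 probes were higher and 6514 lower in high oleic seeds (limma, adjusted p under 0.05), 5229 and 5710 of them by at least 2-fold. The 2 arrays of one line lay on the same side of both arrays of the other for all 12716 called probes; over all tested probes this held for 25622, or 78.1%, where chance gives 33.3%.

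Among the largest differences with a name, the probe most raised in high oleic seeds matched the protein SJCHGC06245 of a flatworm and was at least 20596-fold higher (limma adjusted p = 1.9e-05). Probes matching a bacterial threonine efflux protein, a bacterial FtsE cell division protein and the Brassica rapa sequence 4D11_3 were at least 5139-fold, 3584-fold and 1543-fold higher. The flatworm, threonine efflux and FtsE matches cover only 6%, 5% and 6% of those proteins. Matches so short do not identify a rapeseed gene. Ribosomal proteins L27-2, P1-2 and S30, structural parts of the cytosolic ribosome, were at least 1258-fold, 995-fold and 606-fold higher. The kinase subunit, which acts in the cell cycle, was at least 974-fold higher, At4g12890 at least 718-fold and histone deacetylase 19, a repressor of transcription, at least 501-fold. In the other direction, a probe matched to only 8% of a predicted algal protein was at least 1458-fold lower. Malate dehydrogenase 1 was at least 485-fold lower, At4g05320.3 at least 392-fold and the 10 kDa chaperonin at least 381-fold. Ribosomal protein L4-B was at least 351-fold lower, Sm-D1 at least 199-fold, At1g02300 at least 176-fold, a clathrin coat assembly-like protein at least 152-fold and plastid-specific ribosomal protein 6 at least 131-fold. A probe matched to only 5% of a bacterial fumarate reductase subunit had a log2 difference of -10.19 ± 1.62 (SE, n = 2 per line, limma adjusted p = 0.00581). It was well above background on 1 of the 2 high oleic arrays, and with normexp the difference was -7.31. The bounds hold only for the background-subtracted signal: with normexp the changes of all 38 rule-named probes given as bounds were smaller than the bounds, by 1.00 to 3.37 on the log2 scale. The SJCHGC06245 probe was then 2172-fold higher, that of P1-2 102-fold and that of histone deacetylase 19 55.6-fold.

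**Figure D1:**
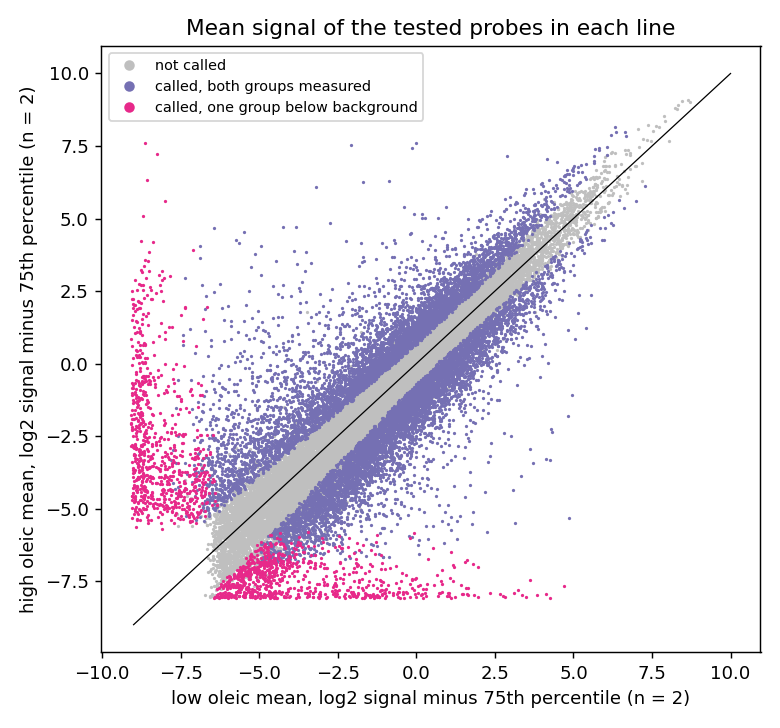
Each point is 1 of 32811 tested probes, with its mean log2 signal relative to the array's 75th percentile in the low oleic line (horizontal axis) and the high oleic line (vertical axis), n = 2 arrays each; the diagonal marks equal means. Called probes below background in 1 line lie along the left and lower edges and number 785 higher and 840 lower in high oleic seeds.

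These counts moved with the arrays used, where a fit with 1 array in a line took its spread from the other line alone. Without high oleic array 2, 20563 probes were called, and without low oleic array 1 or 2 the counts were 7196 and 7590. All differences are relative to the 75th percentile of each array, on which scale the median probe differed by -0.07; relative to the spiked control probes the median was -1.10, and 1255 probes were called higher and 8124 lower (13.4% higher, against 48.8% on the main scale). The median relative to the spiked controls was -0.54 without high oleic array 1 and -1.66 without high oleic array 2. A conflict between deposited tables bears on every comparison here: in the authors' normalized table, the columns headed low oleic line 1 and high oleic line 2 hold, for all 43603 probes within 0.0001, the values that the sample records and scanner files assign to high oleic array 2 and low oleic array 1. The groups used are those of the sample records. With the groups of those headings, limma called 0 probes, and 78 had an unadjusted p under 0.05.

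Desaturases, which introduce double bonds into fatty acid chains, among them those that turn oleic acid into polyunsaturated fatty acids, were examined next. Delta-12 oleate desaturase (FAD2), the enzyme that makes linoleic from oleic acid on the endoplasmic reticulum, had lower transcript signals in high oleic seeds: 3 of its 4 probes fell, by 2.47-fold to 2.63-fold. Of 26 tested desaturase probes 1 was higher, 5 were lower and 20 did not pass, and the counts were the same adjusted over the list alone. Over all tested probes 18.9% were higher and 19.9% lower, so the list did not stand out by its calls. Falls of at least 2-fold were called for 17.4% of all tested probes. The list as a whole was not shifted (camera, adjusted p = 0.501).

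For the FAD2 probe A_46_P234364 the log2 signal was 4.12 ± 0.48 (SD, n = 2) in high oleic and 5.47 ± 0.08 in low oleic seeds, a difference of -1.35 ± 0.30 (SE; limma adjusted p = 0.0162). The probes A_46_P315355 and A_46_P219674 differed by -1.40 ± 0.31 (limma adjusted p = 0.0166) and -1.31 ± 0.35 (limma adjusted p = 0.0302). The remaining FAD2 probe, A_46_P008841, was the brightest and differed by -0.90 ± 0.35, which did not pass (limma adjusted p = 0.0802). Of the omega-6 desaturase probes, which include the plastid enzyme, A_46_P198219 fell by 1.34 on the log2 scale (limma adjusted p = 0.0185) and A_46_P223404 by 0.83 (limma adjusted p = 0.023), while A_46_P264713 differed by -0.73 (limma adjusted p = 0.079). A_46_P198219, the dimmest, and A_46_P264713 share an mRNA record with A_46_P008461, named after its value was seen. This brightest probe of the record differed by -0.40 and did not pass (limma adjusted p = 0.209). A further omega-6 desaturase probe, A_46_P350935, was at least 33.2-fold higher in high oleic seeds, where it was dim, and not well above background in low oleic seeds (limma adjusted p = 0.000129), and 5.18-fold higher with normexp. The chloroplast omega-3 desaturase, which makes linolenic acid, differed by 0.61 ± 0.20 (limma adjusted p = 0.055). The 10 probes of stearoyl-ACP desaturase, which makes oleic acid, ranged from -0.52 to 0.63 and none passed; the one with the smallest p, A_46_P194779, differed by -0.52 ± 0.22 (limma adjusted p = 0.103). All 4 FAD2 probes were lower under every scaling tried. Their mean log2 difference was -1.24 with all arrays, -1.32 without low oleic array 1 and -1.15 without low oleic array 2. Calls from fits with 1 array left out rest on the spread of the other line's pair. The mean was -0.85 without high oleic array 1 and -1.62 without high oleic array 2. Limma called 5 desaturase probes higher and 9 lower without high oleic array 2, among them A_46_P008841, A_46_P264713, A_46_P194779 and the omega-3 probe (limma adjusted p = 0.00392, 0.00421, 0.0126 and 0.0226). The omega-3 probe also passed without high oleic array 1 (limma adjusted p = 0.0219), where 2 desaturase probes were higher. With either low oleic array left out, 1 desaturase probe was higher and 0 lower in limma. With median centring A_46_P219674 and A_46_P223404 did not pass.

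**Figure D2:**
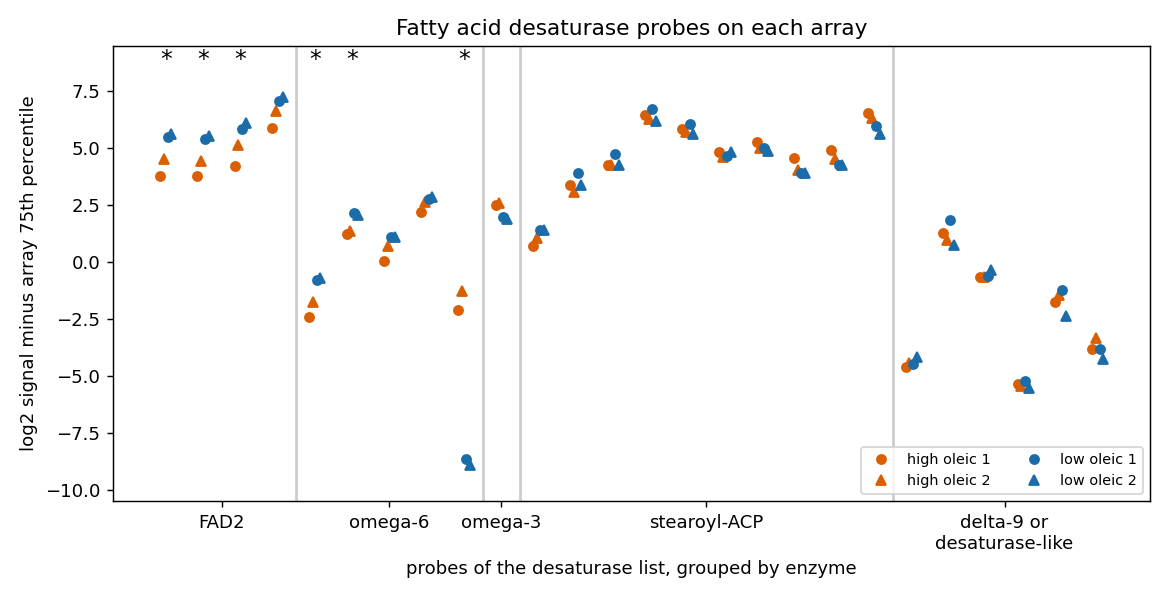
Log2 signal relative to the array's 75th percentile for the 26 desaturase probes (horizontal axis, grouped by enzyme), with 1 point per array; circles are array 1, triangles array 2 and stars mark adjusted p under 0.05 in limma. In the FAD2 group both high oleic arrays lie below both low oleic arrays for each of the 4 probes.

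Of 10 tested probes for fatty acid elongation, which builds very long chains, 6 were lower in high oleic seeds and 0 higher (7 lower adjusted over the list alone), and 4 did not pass. Of the 6, 2 were not well above background in high oleic seeds. The list was shifted down at the preset correlation (camera, adjusted p = 0.00823). With the estimated correlation of 0.151 it was not (camera, p = 0.152). Both probes for At5g10480 were lower in high oleic seeds, with log2 differences of -7.42 ± 0.29 and -4.03 ± 0.33 (SE) (limma adjusted p = 3.2e-05 and 0.000409), and 3-ketoacyl-CoA synthase 10 fell by 2.57 ± 0.28 (limma adjusted p = 0.00146). Over the alternatives, leaving aside the headings and the spiked controls, the smallest differences of the At5g10480 probes were -5.70 and -2.58. The list's median was -1.57, or -0.62 with probes below background in 1 line at their bounds, and -0.01 with the normexp background correction. Limma called 4 of the 10 lower with either low oleic array left out, and 1 higher without high oleic array 1.

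Plastid fatty acid synthesis, which supplies the acyl chains, had 5 probes higher and 8 lower of 36 (5 and 7 adjusted over the list alone; camera, adjusted p = 0.501). Acyl carrier protein 3 and an acyl carrier protein-like gene were higher by 2.46 ± 0.21 and 3.03 ± 0.31 on the log2 scale (limma adjusted p = 0.000469 and 0.00112), and the beta subunit of acetyl-CoA carboxylase was at least 10.2-fold lower (limma adjusted p = 0.00071). With normexp the subunit was 1.79-fold lower. In triacylglycerol assembly 1 probe was higher and 3 lower of 18 (1 and 2 over the list alone; camera, adjusted p = 0.343). The rapeseed DGAT2, which adds the last acyl chain, differed by -1.21 ± 0.28 (limma adjusted p = 0.0199). Lysophosphatidic acid acyltransferase ACT2 differed by 1.81 ± 0.33 (limma adjusted p = 0.00954). Its record describes a chloroplast product, and it is the list's only higher probe. A probe matched to 5% of a bacterial diacylglycerol acyltransferase differed by -2.24 ± 0.32 (limma adjusted p = 0.00379). So short a match does not identify a rapeseed enzyme, although the probe counts among the 3 lower ones. The DGAT2 call was lost without either low oleic array. Plastid synthesis had 7 probes higher and 14 lower without high oleic array 2, 3 and 3 without low oleic array 1, and 3 and 4 without low oleic array 2. Assembly had 2 higher and 9 lower without high oleic array 2, and 1 and 1 with either low oleic array left out.

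Of the oil body proteins, which coat seed oil droplets, 2 of 13 probes were higher and 3 lower (camera, adjusted p = 0.501; fry's direction was down and camera's up). Steroleosin SLO1-3 rose by 2.22 ± 0.37 on the log2 scale (limma adjusted p = 0.00656), while 2 oleosin-like probes were at least 11.3-fold and 3.01-fold lower (limma adjusted p = 0.000429 and 0.0108). With normexp the log2 differences of the oleosin-like probes were -1.03 and -0.09, and the latter did not pass (limma adjusted p = 0.812). Both probes were dim, with mean log2 signals of -2.30 and -4.21 in low oleic seeds. The brightest oleosin probes, named after their values were seen, were not lower. A_46_P320785, A_46_P011421, A_46_P202814, A_46_P195814 and A_46_P202174 differed by 0.57, 0.43, 0.56, 0.45 and 0.39, and none passed in limma. Other, dimmer oleosin probes ranged from -1.25 for A_46_P138584 (limma adjusted p = 0.0481) to 0.77 for A_46_P171899 (not passing). None of the 9 probes for the storage proteins cruciferin and napin passed in limma, and 0 had an unadjusted p under 0.05. The 3 with the smallest p, 2 for cruciferin and 1 for napin, differed by 0.33 ± 0.22, 0.43 ± 0.35 and 0.41 ± 0.28. Limma called 5 of the 9 storage probes and 7 of the 13 oil body probes higher without high oleic array 2, and 1 oil body probe higher without low oleic array 1.

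Of 47 probes for late embryogenesis abundant proteins, which protect seeds as they dry, 11 rose in high oleic seeds and 3 fell (11 and 2 over the list alone). The list was shifted up at the preset correlation (camera, adjusted p = 0.0207). With the estimated correlation of 0.258 it was not (camera, p = 0.426). Both probes for dehydrin Rab18 were bright enough to measure only in high oleic seeds, at least 125-fold and 219-fold higher (limma adjusted p = 3.94e-05 and 4.3e-05), and 16.2-fold and 27.0-fold higher with normexp. GEM-like protein 4, which the list's phrase caught and which is not a late embryogenesis protein, was at least 31.7-fold higher, and 4.94-fold with normexp. With phrases matched from the start of a word, 10 of 42 probes rose and 0 fell. The list's call was lost without high oleic array 1 (camera, adjusted p = 0.171) and with quantile normalization (camera, adjusted p = 0.0532). Of the 47 probes limma called 24 higher without high oleic array 2, and 8 higher and 1 lower without low oleic array 1. Of 4 probes for seed regulators 1 was higher and 1 lower (2 and 1 over the list alone; camera, adjusted p = 0.953). PICKLE, a chromatin remodeller, was 3.26-fold lower (limma adjusted p = 0.0102). A probe for ABI5, a regulator of abscisic acid response, rose by 0.87 ± 0.24 (limma adjusted p = 0.0306), a call lost without either low oleic array; the other ABI5 probe differed by 0.64 ± 0.23 (limma adjusted p = 0.0675). Leaving out high oleic array 1 or high oleic array 2 made this probe pass (limma adjusted p = 0.0484 and 0.0346).

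Lipid breakdown had 1 probe higher and 7 lower of 23 (camera, adjusted p = 0.501). The probes for peroxisomal acyl-CoA oxidase 1, the entry step of beta-oxidation, fell by 1.80 ± 0.33 and 1.27 ± 0.25 on the log2 scale (limma adjusted p = 0.00905 and 0.0112; the latter was lost without low oleic array 2), and the glyoxysomal multifunctional protein was at least 31.9-fold higher (limma adjusted p = 7.48e-05). In carbon supply 3 probes were higher and 9 lower of 31 (camera, adjusted p = 0.203). Pyruvate kinase differed by 1.47 ± 0.24 and enolase by -1.13 ± 0.21 (limma adjusted p = 0.00649 and 0.0101). An enolase-phosphatase, which is not a glycolytic enzyme, was at least 23.3-fold higher, and 4.13-fold with normexp. The pyruvate kinase call was lost without low oleic array 1, and that of enolase without either low oleic array and with median centring (limma adjusted p = 0.0545). Photosynthesis genes went both ways, with 15 probes higher and 10 lower of 70, and 4 and 7 by at least 2-fold (camera, adjusted p = 0.501): chlorophyll a-b binding protein 1 was at least 513-fold higher, a Rubisco N-methyltransferase at least 40.3-fold higher, and the photosystem I apoprotein A1 differed by -2.76 ± 0.24 (limma adjusted p = 1.97e-05, 8.66e-05 and 0.000532). With normexp the binding protein was 52.3-fold and the methyltransferase 5.15-fold higher.

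The counts for these 3 lists moved with the arrays. Lipid breakdown had 5 probes higher and 9 lower without high oleic array 2, 1 and 4 without low oleic array 1, and 1 and 2 without low oleic array 2. In the same order, carbon supply had 3 and 20, 1 and 1, and 2 and 3. Photosynthesis had 27 and 18, 3 and 7, and 3 and 4. The balance of photosynthesis calls turned with the scaling, to 17 higher and 22 lower with quantile normalization (median -0.21) and 2 and 23 relative to the spiked controls.

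The jasmonate and glucosinolate lists, both linked to defence in the cabbage family, held several strongly raised members. Some raised probes, named jasmonate inducible and myrosinase-binding proteins, count in both lists. In the glucosinolate list 10 probes were higher and 3 lower of 23 (11 and 3 over the list alone), and in the jasmonate list 7 were higher and 1 lower of 19; neither shift passed (camera, adjusted p = 0.0676 for each). Epithiospecifier protein, which directs glucosinolate breakdown towards nitriles, was 64.1-fold higher (limma adjusted p = 9.51e-05), and 2 myrosinase-associated protein probes were at least 9.59-fold and 6.01-fold higher. A pair of jasmonate inducible proteins was higher by 4.01 ± 0.42 and 2.05 ± 0.34 (limma adjusted p = 0.00119 and 0.00663), and a lipoxygenase by 1.72 ± 0.25 (limma adjusted p = 0.0043). The jasmonate probe called lower, A_46_P354530, named after its value was seen, also matched a jasmonate inducible protein and was at least 5.46-fold lower (limma adjusted p = 0.0115). Without high oleic array 1 both lists were called (camera, adjusted p = 0.0235 for jasmonate and 0.0349 for glucosinolates). Without low oleic array 2 the jasmonate list passed at 0.0457 and the glucosinolate list at 0.00463, and the latter also passed without low oleic array 1, at 0.0134 (camera, adjusted p). With 1 probe per gene name the glucosinolate median was -0.13 (camera, adjusted p = 0.937) and the jasmonate list had an adjusted p of 0.38 in camera. Both lists passed with normexp, at 0.0397 for glucosinolates and 0.0174 for jasmonate (camera, adjusted p). The replicate block gave 0.00892 for glucosinolates, and the jasmonate list passed at 0.012 for probes detected on all arrays and at 0.023 with probes below background in 1 line left out (camera, adjusted p). Relative to the spiked controls glucosinolates passed at 0.0111 (camera, adjusted p). Probes lower numbered 6 for glucosinolates without high oleic array 2 and 1 without low oleic array 2, and 2 for jasmonate without low oleic array 1.

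Heat shock proteins had 6 probes higher and 18 lower of 56 (6 and 19 over the list alone; camera, adjusted p = 0.297). A heat shock transcription factor-like gene and a class I small heat shock protein were at least 450-fold and 121-fold higher, and a 70 kDa heat shock protein differed by -3.91 ± 0.37, with signal above background on 1 of the 2 high oleic arrays (limma adjusted p = 1.98e-05, 0.000502 and 0.00082). With normexp that difference was -0.88, the factor-like gene was 45.9-fold higher and the small heat shock protein 15.4-fold higher. The factor-like probe matches only 9% of its Arabidopsis protein. The defence list had 11 probes higher and 7 lower of 60 (7 and 2 over the list alone; camera, adjusted p = 0.823). Disease resistance protein RPP8 was at least 4.07-fold higher (limma adjusted p = 0.00174), and 2.04-fold with normexp. A chitinase was higher by 5.19 ± 0.61, measured on 1 of the 2 low oleic arrays (limma adjusted p = 0.00193), and by 2.62 with normexp. The list's probe with the smallest p was a methionine sulfoxide reductase, a repair enzyme caught by the list's phrase, at 2.02 ± 0.20 (limma adjusted p = 0.00101). Heat shock had 16 probes higher and 19 lower without high oleic array 2, and 6 and 10 without low oleic array 1. Defence had 13 and 20 without high oleic array 2, 5 and 1 without low oleic array 1, and 7 and 4 without low oleic array 2. The heat shock list passed without high oleic array 1 (camera, adjusted p = 0.0349).

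Cytosolic ribosomal proteins were shifted up in high oleic seeds: of 343 probes 102 rose, 20 fell and 221 did not pass (100 and 18 called over the list alone; camera, adjusted p = 3.7e-06; p = 0.544 with an estimated correlation). Next to S30 and L27-2, whose further probe was higher by 11.09 ± 0.36 (7.83 with normexp) and measured on 1 low oleic array, L7a-2 was at least 342-fold higher (limma adjusted p = 1.98e-05). With normexp L7a-2 was 40.7-fold higher. The median of the list was 0.54 (0.27 without high oleic array 1 and 0.82 without high oleic array 2), and it was -0.49 relative to the spiked controls, on which scale the medians of all 19 lists lay below 0. On that scale 21 ribosomal probes were higher and 32 lower. Cell division genes had 23 probes higher and 22 lower of 121 (camera, adjusted p = 1.00), and 6 and 32 relative to the spiked controls. Beside the kinase subunit, histone H3.2 was at least 28.2-fold lower and a histone H2A variant higher by 3.83 ± 0.28 (limma adjusted p = 0.000244 and 0.000289). With normexp histone H3.2 was 4.21-fold lower. Limma called 215 ribosomal probes higher and 25 lower without high oleic array 2, 59 and 12 without low oleic array 1, and 50 and 12 without low oleic array 2. Cell division had 37 and 30, 12 and 3, and 11 and 23 in the same order. Leaving out high oleic array 1 gave 31 lower ribosomal and 14 lower cell division probes.

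Markers of other tissues were also measured. Seed coat pigment genes had 7 probes higher and 0 lower of 25 in high oleic seeds (camera, adjusted p = 0.297). Anthocyanidin synthase was higher by 3.26 ± 0.38 on the log2 scale, a chalcone-flavonone isomerase by 2.36 ± 0.36, and a leucoanthocyanidin dioxygenase-like gene at least 4.59-fold (limma adjusted p = 0.00184, 0.0052 and 0.00685). With normexp the dioxygenase-like gene was 1.85-fold higher. Limma called 7 seed coat probes higher and 7 lower without high oleic array 2, with a median of 0.04. Leaving out high oleic array 1 it called 11 higher and 0 lower and the list passed (camera, adjusted p = 0.0349), and without low oleic array 1 or 2 it called 4 and 5 higher and 0 and 1 lower. Of 4 probes for the silique wall or leaf 1 was higher (camera, adjusted p = 0.501): a chloroplast carbonic anhydrase at 2.69 ± 0.37 (1.07 with normexp), measured on 1 low oleic array (limma adjusted p = 0.00356). A pair of other carbonic anhydrase probes differed by -0.62 ± 0.22 and 0.74 ± 0.36 (limma adjusted p = 0.0663 and 0.148), and both passed without high oleic array 2 (limma adjusted p = 0.0233 and 0.00897). Relative to the spiked controls the calls were 1 higher and 4 lower for seed coat, 3 and 14 for defence, 6 and 4 for late embryogenesis, 5 and 4 for glucosinolates and 2 and 1 for jasmonate. They were 0 and 11 for plastid fatty acid synthesis (5 and 12 with quantile normalization), 0 and 6 for triacylglycerol assembly, 1 and 14 for carbon supply, 2 and 22 for heat shock, 1 and 11 for desaturases, 1 and 8 for lipid breakdown and 0 and 7 for elongation. Oil body proteins had 0 and 3, storage proteins and seed regulators 0 and 1 each, and the silique or leaf list 0 and 0. With an estimated correlation none of the 19 lists passed in camera, where the smallest unadjusted p was 0.152, for elongation. None passed with fry either (smallest adjusted p in fry 0.0575). For lipid breakdown fry's direction was up and camera's down.

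**Figure D3:**
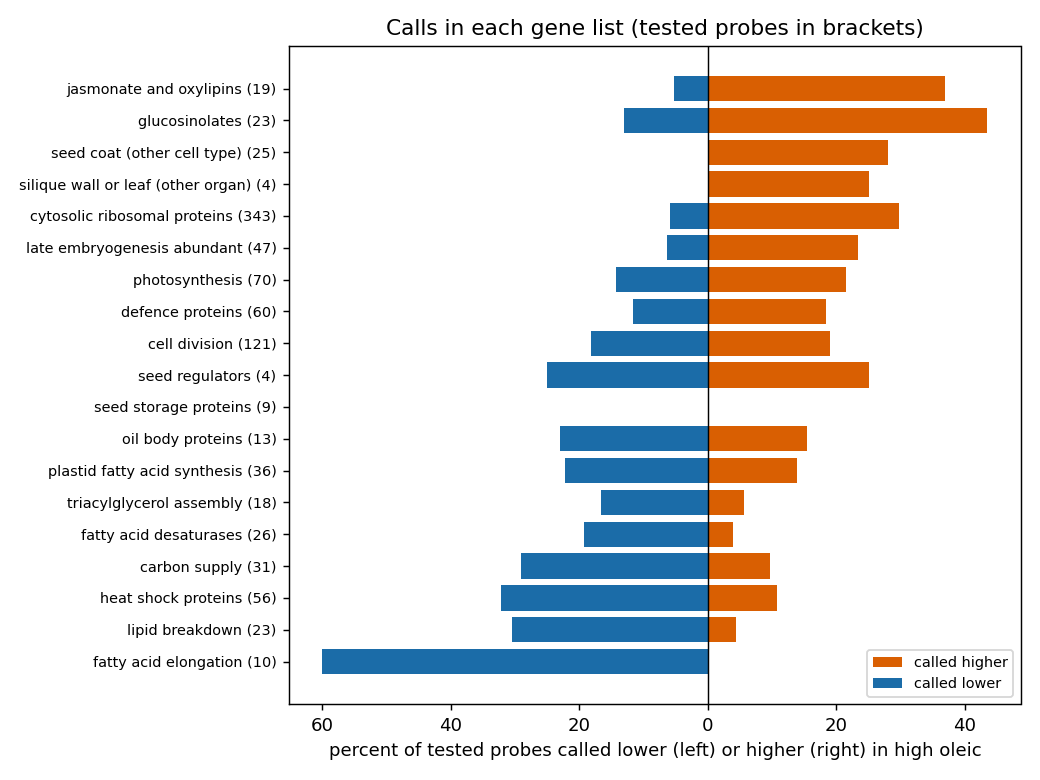
Percent of each list's tested probes called higher (right) or lower (left) in high oleic seeds at an adjusted p under 0.05 in limma; the number of tested probes is in brackets. Fatty acid elongation has 6 of 10 probes lower and glucosinolates 10 of 23 higher. Over all tested probes 18.9% were higher and 19.9% lower.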

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

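Of the tests below, that of a switch between gene copies and that of the scaling of the oleate desaturase were chosen before their results were seen; the others were chosen after.

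Spiked control probes (E1A), which the comparisons above do not use, were brighter relative to the rest of the array in high oleic seeds: the 8 of 10 well above background on all arrays differed by 1.03 on the log2 scale after scaling on the 75th percentile. After scaling it was 0.49 without high oleic array 1, the dimmest, and 1.57 without high oleic array 2. Before scaling the difference was 0.34, and 7 of the 8 were brighter on both high oleic arrays than on both low oleic arrays.

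A set of 668 called probes, 448 higher and 220 lower in high oleic seeds, differed by at least 8-fold with one line not well above background. The lowest detected log2 signals were -5.36 and -6.24 on the high oleic arrays and -6.55 and -6.92 on the low oleic arrays. Probes dim in low oleic seeds thus reach such a bound at a lower signal, which favours higher calls. Detection ran the other way, with 788 probes detected on both high oleic arrays alone and 1360 on both low oleic arrays alone. With normexp all 668 were called the same way, 217 of them by at least 8-fold. Array brightness cannot give such bounds by itself, since the brightest array exceeded the dimmest by 2.29-fold at the 75th percentile. Sequence differences under single probes are argued against for the 70 with another tested probe of the same source sequence and stay open for the other 598: of 77 such probes, 71.4% (Wilson 95% interval 60.5 to 80.3) were called the same way by at least 2-fold, against 16.6% of all probes, although probe positions are not known and neighbours could overlap. A switch between gene copies could not be told apart from chance: 35.4% of 127 such probes had a copy of the same product name called the opposite way, against 25.2% to 39.4% in 1000 random draws. Line-specific expression, presence or absence of whole genes may account for the set and stays open.

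Delta-12 oleate desaturase was lower in high oleic seeds. The choice of scaling does not account for it, since the mean log2 difference of its 4 probes was -1.05 or lower under every other scaling. Seeds at an earlier filling stage cannot be told apart from a difference between the lines, because the median of the storage protein probes depends on the scaling and on single arrays: 0.33 here, -0.09 with quantile normalization, -0.71 relative to the spiked controls, 0.07 without high oleic array 1 and 0.68 without high oleic array 2. The same holds for seeds at a later stage, since the shift of the late embryogenesis list passed only with the preset correlation. The list's median was 0.46 here and -0.57 relative to the spiked controls. It was 0.16 and 0.79 without high oleic array 1 or 2, and 0.28 without low oleic array 2. The oleic acid content for which the lines are named, and the transgene, stay open as untested explanations.

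The headings of the normalized table cross 2 arrays. Were they right and the sample records wrong, arrays under the same heading should resemble each other most, yet the mean correlation within those groups was 0.814, and the difference from that between them was -0.083. This argues against the headings unless something other than the line, such as seed age, separates the arrays. A swap of both arrays of each line could not be seen in this way.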

How the results depend on the processing

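Normexp on the median signal, scaling on spiked controls, word-start phrases and lists without probes below background in 1 line were chosen after seeing the data. Across scalings, filters and variance models other than those named here, counts of called probes stayed within 1.5 times 12716 (6202 higher, 6514 lower). Leaving out each array gave 7196 to 20563 called probes (3599 to 9602 higher, 3597 to 10961 lower), 1 to 14 called desaturase probes against 6, and 3 to 6 called lists against 3; a lone array was assumed to vary like the other line. Scaling on spiked controls gave 9379 called probes, of which 1255 were higher, and 12 called desaturase probes. The median of all probes was -1.10 on that scale, but whether this shift alone gave these counts was not tested. An adjusted p under 0.01 called 4712 probes, 2760 higher and 1952 lower. A plain two-sample test called 2 after adjustment, 1 higher and 1 lower, and 9674 at an unadjusted p under 0.05. With the groups of the normalized table's headings, 0 probes were called, 0 higher, 0 lower and 0 desaturases, and camera called 6 lists; of single genes only the FAD2 mean was recomputed there (-0.62). Lists called numbered 5 with normexp and 0 with members by locus only, where 1 list had enough probes. Leaving aside the headings and the spiked controls, elongation and ribosomal proteins were called in 17 of 17 alternatives. Late embryogenesis was called in 11 of 17. These alternatives all keep camera's preset correlation. With fry the 3 lists did not pass (fry, adjusted p = 0.0575 for elongation, 0.227 for ribosomal proteins and 0.138 for late embryogenesis). Nor did they pass with an estimated correlation (camera, adjusted p = 0.829 for each). With the spiked controls all 3 were called, and with the headings elongation was not (camera, adjusted p = 0.338). For late embryogenesis the adjusted p was 0.0532 with quantile normalization, 0.119 for probes detected on all arrays, 0.158 with 1 probe per gene name and 0.171 without high oleic array 1. With probes below background in 1 line left out, late embryogenesis had an adjusted p of 0.0883. The mean correlation between the lines was 0.813, and 0.873 with normexp, 0.867 for probes detected on all arrays and 0.901 with no filter. A cruciferin probe (A_46_P009811), not called at 0.43, reversed to -0.13 with quantile normalization and -0.16 with the series values. Of 12716 called probes, 610 changed sign with normexp; except where said, the cause was not tested.

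The replicate number as a block gave 15131 called probes (6987 higher, 8144 lower), 7 desaturases and 4 lists; the numbers do not pair the arrays, since the deviations of replicates 1 and 2 correlated at 0.0147 between the lines. Normexp on the mean signal was not run, because the files hold no such column, nor was the slide as a block, with 1 slide. Low signal limits the comparison: 8251 probes were well above background on no array.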

Other observations

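The genes described here were chosen after their values were seen. Within fatty acid elongation 9 of the 10 probes had negative log2 differences and FAE1 was the exception. FAE1, the condensing enzyme that makes erucic acid in rapeseed, differed by 0.39 ± 0.25 (SE) between high and low oleic seeds and did not pass (limma adjusted p = 0.253), whereas 3-ketoacyl-CoA synthase 4, of the same enzyme family, fell by 2.28 ± 0.40 on the log2 scale (limma adjusted p = 0.00828). The synthases 11 and 16 differed by -0.34 ± 0.38 and -0.90 ± 0.38 and did not pass (limma adjusted p = 0.491 and 0.104). Synthases 8 and 14 were called lower, but were not well above background in high oleic seeds, and the bound for the latter was at least 1.11-fold.

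Probes of the glucosinolate list went both ways, also within a product. Myrosinase, the enzyme that splits glucosinolates, had 2 called probes, both lower in high oleic seeds, with log2 differences of -1.29 ± 0.27 and -1.41 ± 0.34 (limma adjusted p = 0.0149 and 0.0212). Further epithiospecifier probes were higher by 3.50 ± 0.68 and 0.87 ± 0.26 (limma adjusted p = 0.0112 and 0.0424), and another differed by 0.18 ± 0.26 (limma adjusted p = 0.6). A set of 4 probes for jasmonate inducible, myrosinase-binding proteins, which count in both the jasmonate and glucosinolate lists, was higher by 2.58 to 2.70. Of these, 1 was measured on 1 of the 2 low oleic arrays. A rapeseed myrosinase binding protein went the other way, at -1.60 ± 0.44 (limma adjusted p = 0.0311). The other myrosinase probes differed by 0.44 ± 0.24 and -0.56 ± 0.32 and did not pass (limma adjusted p = 0.18 and 0.205). Further anthocyanidin synthase probes were higher by 2.03 ± 0.38 and 1.23 ± 0.25 (limma adjusted p = 0.00997 and 0.0127).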
